A study of Homo sapiens with 6 samples.

How the data were processed

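RNA was sequenced from IMR90 cells, a strain of normal human lung fibroblasts, in 3 groups of 2 libraries: proliferating cells, cells treated with etoposide and carrying a non-targeting short hairpin RNA (sh-NTC), and cells treated with etoposide and carrying a hairpin against cGAS (sh-cGAS). Etoposide is a topoisomerase II poison that leaves DNA double-strand breaks. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into strand-specific libraries that were run on a NextSeq 500. The series text calls the replicates independent biological replicates. The labels give the proliferating libraries no hairpin, so a comparison with them changes the drug, the hairpin and the time in culture together. The labels give no batch of library preparation or sequencing. The proliferating libraries differ from the etoposide libraries in depth and in ribosomal RNA share, and a separate batch, if there was one, cannot be told apart from these groups.

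The deposited values are raw read counts per gene symbol, per the file headers, which name refGene as the annotation. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned to the hg19 genome with STAR 2.3.0e and counted with featureCounts 1.5.0, and DESeq2 was used without a stated version. The strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. Antisense genes, overlapping genes and genes with near-identical copies are therefore reported as uncertain. The 2 columns whose names carry the letters SC with etoposide were taken as the sh-NTC libraries by elimination, since no title carries those letters and every other column name matched a title. All columns of values were used. The file held 27135 entries, of which 3245 had no count in any library. Another 27 had date-like names, 2 of the dates occurring on 2 entries each; these stayed in the tests and are not named.

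The reference annotation at hand was GENCODE release 29 on another genome build than hg19, so no coordinates are given. It served for transcript lengths, found for 24287 of 27133 distinct names (89.5%), and for the number of processed pseudogenes of ribosomal protein and other genes.

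Counts were tested with edgeR 4.0.16 in R 4.3.3. Entries passing filterByExpr by group (minimum count 10, minimum total 15) were kept, which left 13998. Library sizes were scaled by TMM, which adjusts totals for composition. A quasi-likelihood model with a term per group was fitted to all 6 libraries, leaving 3 residual degrees of freedom, and each pair of groups was compared by a two-sided F-test with Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. Levels are CPM (counts scaled to a common library total) on TMM-scaled library sizes, as mean ± SD of 2 libraries. Confidence intervals of ratios against a group with 1 to 3 counts are exact (Clopper-Pearson) at 95%, and the floor of a library is 3 counts, which is 0.0768 to 0.308 CPM. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

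Gene lists were tested with camera from limma 3.58.1 with an inter-gene correlation of 0.01, adjusted over the 24 lists with at least 2 tested members. Because genes of one list move together, each test was repeated with the correlation estimated from the data, and with fry, which asks whether the genes of a list move one way on balance. No list passed in any comparison with an estimated correlation. That form of the test rests on the residual degrees of freedom, 3 in 6 libraries and 2 in the 4 etoposide libraries, and so has little power. Even the G2/M list, most of whose members passed singly in sh-NTC against proliferating cells, did not pass it. Its adjusted p-values therefore do not show that a list was unchanged, while the fixed correlation of 0.01 may be too low for genes that move together. No list median changed when genes with 0 counts in a group were set at their bound. Of the 25 lists, these cover the cGAS-STING pathway, secreted cytokines, chemokines and growth factors of senescent fibroblasts, secreted proteases and their regulators, interferon-stimulated genes, other NF-kB target genes, antigen presentation, p53 target genes, cell cycle inhibitors and arrest markers, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, nuclear lamina and chromatin proteins that decline in senescence, homologous recombination and Fanconi genes, lysosome, extracellular matrix, contractile and TGF-beta/YAP-responsive genes, cholesterol synthesis, immediate early and stress response, ribosomal proteins, abundant non-coding RNA, and markers of epithelial, endothelial, leukocyte and smooth muscle cells. The remaining list, mitochondrially encoded mRNA, had 0 entries in the file.

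The groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule takes 18 genes known in advance (cGAS and markers of senescence and inflammation), the 5 largest and 5 smallest log2 fold changes among genes that passed, had a mean of at least 50 counts and did not overlap between groups in CPM, and up to 3 members of each list by the same conditions. It leaves out XIST, Y-linked genes and entries named as uncharacterised loci or small RNA. One gene that the rule takes is not reported here. Genes named outside that rule, because a count was 5 or fewer, were chosen after their values were seen and are marked so. Because no gene passed between the etoposide groups in all 6 libraries, the largest-change and list parts of the rule were applied there to the fit of the 4 etoposide libraries, a choice made after seeing the data.

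The alternatives planned in advance were DESeq2 1.42.0, limma-voom, the older edgeR quasi-likelihood method, RLE factors (the size factors DESeq2 uses), library totals without factors, no filter on low counts, at least 1 CPM in at least 2 libraries, only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. When a library is left out, its group's remaining library is assumed to vary like the other groups. DESeq2 was run on all entries, without the low-count filter used for edgeR, so its counts of calls cover more entries. Added after seeing the data were removal of the ribosomal RNA entries, removal of a smooth trend on transcript length (lowess span 0.3), DESeq2, leave-outs, length correction and list tests in the 4 etoposide libraries, and overlaps with the calls made there.

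Counts were simulated from real library sizes and each gene's mean over all groups. The procedure was tested on them with 100 genes changed by a log2 fold change of 1 and 100 by 3. For sh-NTC against proliferating, edgeR recovered 3% and 78% of them, with 14 unchanged genes called among 13771 tested. Beside 3 and 78 recovered genes, these were a larger share of the calls than the adjusted p threshold allows on average. DESeq2 recovered 13% and 90% there, with 81 unchanged genes called among 13998, a larger share still. For sh-cGAS against sh-NTC, edgeR recovered 0% and 86% in 6 libraries (1 unchanged gene called among 13777) and 31% and 95% in the 4 etoposide libraries (10 among 13476). DESeq2 recovered 8% and 92% in 6 libraries there, with 2 unchanged genes called. The spread was more alike across simulated genes than across real ones (prior degrees of freedom 7.69 against 4.29 in 6 libraries). The recovered shares may therefore be too high for the real data. A changed simulated list had a camera adjusted p of 1.81e-23, and 0 of 24 unchanged lists passed. Simulated genes were drawn independently and the lists were random. This result therefore cannot show how often camera calls unchanged lists whose genes move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.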

Results

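Whole-transcriptome RNA counts were obtained from 6 libraries of IMR90 fibroblasts. In the etoposide groups, 50 µM of the drug was present for 48 h, the medium was then replaced, and RNA was taken on day 7. Cells of these groups carried either a non-targeting hairpin (sh-NTC) or a hairpin against cGAS (sh-cGAS), the cytosolic DNA sensor that makes the messenger cGAMP and activates STING. The proliferating pair carries the labels PD29 and PD34. Total counts were 34790674 and 39082184 in the proliferating libraries, 9755125 and 10518038 in etoposide sh-NTC, and 10046443 and 12744127 in etoposide sh-cGAS. Ribosomal RNA entries (RNR1, RNR2 and RNA45S5) took 1.68% and 0.0524% of counts in the proliferating libraries, 27.8% and 17.2% in sh-NTC, and 20.7% and 14.1% in sh-cGAS. RNR1 and RNR2 together took 0.338% and 0.00987%, 23.9% and 12.8%, and 19.0% and 10.5% in the same order, most of the share in the etoposide libraries. Abundant non-coding RNA, set against the counts without any ribosomal RNA entry, came to 2.28% and 0.658%, 6.37% and 5.75%, and 2.77% and 4.55% in the same order. That list includes 1 of the ribosomal RNA entries, which alone took 1.35% and 0.0425%, 3.91% and 4.4%, and 1.7% and 3.57% of all counts.

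The proliferating pair differed more between its libraries than either etoposide pair. Of 13998 genes tested, 27.2% lay over 2-fold apart between the proliferating libraries, against 8.04% in sh-NTC and 6.33% in sh-cGAS. The common dispersion was 0.190, 0.0473 and 0.0293 in the same order. The first principal component held 55.3% of the variance and separated proliferating from etoposide libraries, and the second held 19.7% and ran from sh-NTC replicate 1 to sh-cGAS replicate 2, with the proliferating libraries on either side of 0.

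The hairpin target itself, cGAS (listed as MB21D1), had 225 and 358 counts in the proliferating libraries, 50 and 72 in sh-NTC, and 16 and 25 in sh-cGAS. Its level was 8.09 ± 0.0607 CPM in proliferating cells, 5.66 ± 0.342 CPM in sh-NTC and 1.77 ± 0.183 CPM in sh-cGAS (SD, n = 2 each). The sh-cGAS level was 31.5% of sh-NTC (log2 fold change -1.67, SE 0.32), lower in both libraries than in both sh-NTC libraries. The edgeR adjusted p of that difference was 0.187 over all genes and 0.0183 adjusted over the list alone. In the 4 etoposide libraries it was 0.0431, within a range of 0.00507 to 1 over 24 alternatives in which the log2 fold change stayed between -1.77 and -1.55. Against proliferating cells, cGAS fell by 2.18 on the log2 scale in sh-cGAS (SE 0.32, edgeR adjusted p 0.0155, range 3.36e-04 to 0.150), whereas the sh-NTC value of -0.51 (SE 0.30) did not pass (adjusted p 0.284).

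Etoposide sh-NTC cells, with RNA taken on day 7, were compared with proliferating cells, from which they differ in drug, hairpin and time in culture. Of the genes of G2/M and mitosis 64 of 69 fell, of G1/S and DNA replication 31 of 49, and of replication-dependent histones 41 of 53 (adjusted p = 0.315, 0.315 and 0.316 for these lists with an estimated correlation). LMNB1, which encodes lamin B1 and declines in senescent cells, fell from 117 ± 3.88 to 8.36 ± 1.86 CPM (SD, n = 2 each). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 147 ± 71.3 to 622 ± 112 CPM. The metalloproteinase genes MMP3 and MMP1, with products that degrade matrix proteins, rose by log2 fold changes of 10.74 (SE 0.88) and 4.82 (SE 0.60). Of 37 extracellular matrix genes 11 fell (adjusted p = 0.573 for the list with an estimated correlation). Without sh-NTC replicate 1, 0 members of these 4 lists passed, and of the single genes named here MMP3 did.

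Between these groups 882 genes were higher and 941 lower among 13998 tested (edgeR, adjusted p under 0.05). DESeq2, without the low-count filter, called 1149 higher and 1603 lower among 23890 entries, a share of higher calls of 41.8% against 48.4%. Among the 13998 genes that edgeR tested, 922 of these calls were higher and 1598 lower, so the shares cover unlike sets of genes. In simulated counts of this comparison DESeq2 called 81 unchanged genes against 14 by edgeR, so its larger counts may hold more false calls. The edgeR counts fell when any etoposide library was left out, sh-cGAS libraries included, and fell furthest without sh-NTC replicate 1. A group left with 1 library adds nothing to the estimated spread, so these falls do not show that the changes rest on the sh-NTC pair. Without sh-NTC replicate 1 all 68 genes named by the rule and called kept the sign of their log2 fold change. The genes that passed without it were MMP3, RPL7, RASGRP3, ALB and AKR1B10, the last 3 chosen after their values were seen. Without a proliferating library the counts rose, to 1828 and 1863 without replicate 1 and to 2420 and 2910 without replicate 2. They fell to 329 and 345 without sh-cGAS replicate 1, to 302 and 336 without its replicate 2, and to 368 and 356 with the sh-cGAS group left out. Scaling by library totals alone shifted the median of all genes by 0.13. The proliferating libraries also differ from the etoposide libraries in depth, in ribosomal RNA share and in having no hairpin in their labels.

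Of 69 tested genes of G2/M and mitosis, 64 fell and 0 rose (0 and 68 higher and lower adjusted over the list alone), with a median log2 fold change of -2.88 and a camera adjusted p of 2.8e-57 (adjusted p = 0.315 with an estimated correlation). MKI67, a marker of cycling cells, fell by 4.29 (SE 0.57), and MYBL2, a transcription factor of cycling cells, by 4.75. ASPM and KIF20A, which act at the mitotic spindle and in cytokinesis, fell by 4.36 and 4.29. Of 49 genes of G1/S and DNA replication, 31 fell and 1 rose (41 and 1 adjusted over the list alone, median -1.59, camera adjusted p 1.19e-18; adjusted p = 0.315 with an estimated correlation). Thymidine kinase TK1 fell by 4.19 and the ribonucleotide reductase subunit RRM2 by 2.98, and the gene that rose was E2F7, a repressor of E2F targets, by 1.28. Replication-dependent histone genes fell in 41 of 53 cases (48 adjusted over the list alone, median -2.88, camera adjusted p 2.39e-34; adjusted p = 0.316 with an estimated correlation), led by HIST1H3B at -4.49. Histone genes are near-identical copies, so the split of reads among them is uncertain. Of 23 homologous recombination and Fanconi genes, 14 fell, among them FANCD2 (-2.67) and BLM (-2.60), with 18 adjusted over the list alone, a median of -1.70 and a camera adjusted p of 1.28e-11 (adjusted p = 0.316 with an estimated correlation). Without sh-NTC replicate 1, 0 members of these lists passed, with medians of -2.45, -1.39, -2.64 and -1.42 in the order above. Without its replicate 2, 51, 9, 20 and 5 members were lower, and the camera calls stayed past the threshold without any single library.

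Of 40 tested p53 target genes, 11 rose and 0 fell (14 and 1 adjusted over the list alone), with a median of 0.78 and a camera adjusted p of 4.58e-07 (adjusted p = 0.201 with an estimated correlation). CDKN1A rose by 2.08 (SE 0.44, edgeR adjusted p 0.0265, range over alternatives 2.75e-05 to 0.148). PTCHD4 rose by 2.27 and RRM2B, a ribonucleotide reductase subunit induced by p53, by 2.22. Of the 16 cell cycle inhibitors and arrest markers, CDKN1A and CDKN2A rose, while CDKN2C (-2.71) and RBL1 (-2.29) fell (3 higher and 4 lower adjusted over the list alone), with no call for the list (median -0.46, camera adjusted p 0.213). CDKN2A, which encodes the inhibitor p16 and the protein ARF, rose from 2.93 to 6.34 CPM (log2 fold change 1.11, SE 0.29, adjusted p 0.0492), but its range over the alternatives was 0.0247 to 0.233, and DESeq2 gave 0.105. Of 20 genes of lamina and chromatin proteins that decline in senescence, 10 fell (11 adjusted over the list alone, median -1.10, camera adjusted p 9.15e-08; adjusted p = 0.315 with an estimated correlation), among them LMNB1 (-3.80, SE 0.35), HMGB2 (-2.96, SE 0.47) and LBR (-2.67). Without sh-NTC replicate 1, 0 members of these 3 lists passed, and without its replicate 2, 2 p53 targets and 1 lamina gene did.

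Secreted cytokines, chemokines and growth factors of senescent fibroblasts had a median log2 fold change of 2.40, and 8 of 32 tested members rose and 1 fell (19 and 3 adjusted over the list alone, camera adjusted p 9.27e-06; adjusted p = 0.573 with an estimated correlation). The neutrophil chemokine CXCL5 rose by 8.90 (adjusted p 0.024). IL33, an alarmin of the interleukin-1 family, had 0 and 1 counts in proliferating cells against 197 and 35 in sh-NTC, a ratio of 779 with a counting interval of 139 to 30913. CSF1, the macrophage growth factor, fell by 2.58. The interleukins and chemokines best known from senescent fibroblasts did not pass in edgeR: the log2 fold change was 4.35 for IL1A (adjusted p 0.0688), 4.49 for IL1B (0.125), 3.11 for IL6 (0.214), 4.98 for CXCL8 (0.111), 5.53 for CXCL1 (0.109) and 0.56 for CCL2 (0.766). These values without sh-NTC replicate 1 were 0.82 for IL1A, 0.95 for IL1B, -1.14 for IL6, 1.41 for CXCL8, 0.75 for CXCL1 and -2.27 for CCL2, and the CCL2 value was -0.04 without proliferating replicate 2. IL1A passed without sh-NTC replicate 2 (adjusted p 0.0263), and IL1B (0.0317) and CXCL8 (0.0381) without proliferating replicate 2, within ranges of 0.00222 to 0.632, 0.0108 to 0.744 and 0.00829 to 0.613 over the alternatives. The adjusted p ran from 0.0462 to 0.639 for IL6 and from 0.00584 to 0.806 for CXCL1, both lowest and under the threshold with library totals alone, and from 0.296 to 0.983 for CCL2. Their counts differed widely within sh-NTC, with 5785 and 351 for IL1B, 4862 and 177 for IL6, and 63538 and 3765 for CXCL8 in replicates 1 and 2. The proliferating counts were 47 and 1208, 464 and 2031, and 471 and 9286 for the same 3 genes. Without sh-NTC replicate 1, 0 members passed and the list's median was 0.85, and without its replicate 2, 12 were higher with a median of 3.21.

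**Figure D1:**
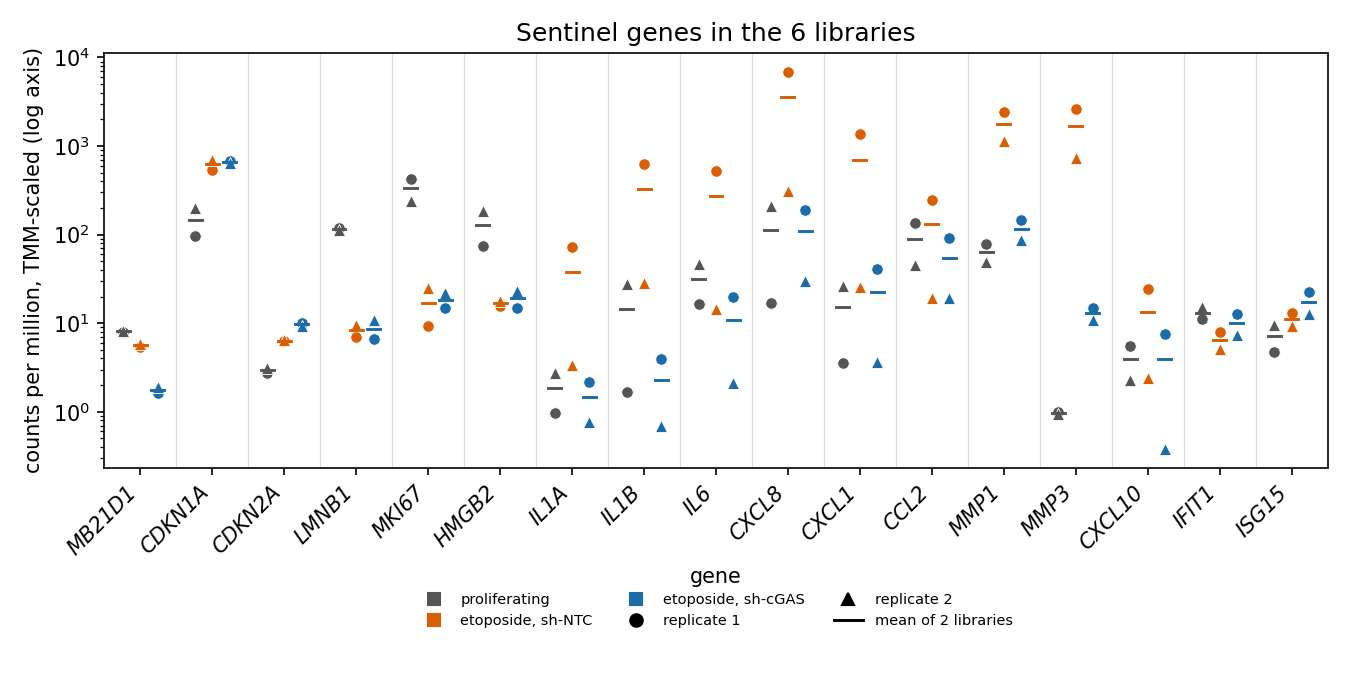
TMM-scaled CPM, on a log axis, of 17 genes chosen in advance, in each library; colour gives the group, circles and triangles give replicates 1 and 2, and lines give the mean of 2. MMP3 lies at 1677 CPM in sh-NTC against 0.978 in proliferating and 12.9 in sh-cGAS, and the interleukin and chemokine genes lie apart between the sh-NTC replicates.

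Other NF-kB target genes had a median of 0.72, with 7 of 35 higher and 1 lower (11 and 2 adjusted over the list alone, camera adjusted p 0.00578; adjusted p = 0.81 with an estimated correlation). The apoptosis inhibitor BCL2A1 rose by 6.62 and the prostaglandin synthase gene PTGS2 by 5.34, and the syndecan gene SDC4 fell by 2.65. The camera call was lost without proliferating replicate 1 (adjusted p 0.0591), proliferating replicate 2 (0.0923) or sh-NTC replicate 1 (0.542), within a range of 7.17e-13 to 0.81 over the alternatives. Among 25 secreted proteases and their regulators, 6 rose and 2 fell (6 and 6 adjusted over the list alone), with a median of 0.03, a mean of 0.93 and no call (camera adjusted p 0.0829). MMP10 rose by 5.80 beside MMP1 and MMP3, and IGFBP3, which binds insulin-like growth factors, fell by 2.05, as did IGFBP6, chosen after its values were seen. That list passed without proliferating replicate 1 (adjusted p 7.2e-04), sh-NTC replicate 2 (2.26e-05) or sh-cGAS replicate 1 (0.0193) or 2 (0.0163), within a range of 2.26e-05 to 0.81.

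Interferon-stimulated genes did not pass as a list (median -0.17, camera adjusted p 0.127), with 0 of 42 tested members higher and 3 lower (0 and 2 adjusted over the list alone). The 3 were UBA7 (-2.69), the enzyme that activates ISG15 for conjugation, GBP1 (-1.92) and EPSTI1 (-1.81). IFIT1 had a log2 fold change of -1.01 (adjusted p 0.126), ISG15 of 0.64 (0.362) and CXCL10 of 1.75 (0.391), which became -0.74 without sh-NTC replicate 1. IFNB1, which encodes interferon beta, had 2, 0, 0, 1, 0 and 0 counts across the 6 libraries and was not tested, so a difference was not detectable at this depth. Antigen presentation genes were lower as a list (median -0.70, camera adjusted p 0.0158; adjusted p = 0.733 with an estimated correlation), with PSMB9 (-2.25) and ERAP1 (-2.04) the 2 of 22 that fell and 0 adjusted over the list alone. That call was lost without proliferating replicate 1 (0.206) or sh-NTC replicate 2 (0.0999), within a range of 8.24e-04 to 0.733. Of 17 cGAS-STING pathway genes, IFI16, a nuclear DNA sensor, fell by 1.49, RNASEH2A, a subunit of ribonuclease H2, fell by 2.11, and 0 rose (0 and 2 adjusted over the list alone). The list's median of -0.03 did not pass (camera adjusted p 0.694) and turned positive with library totals alone. The interferon list passed without the low-count filter (0.0134) and without sh-NTC replicate 1 (0.017), within a range of 0.0134 to 0.81.

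Extracellular matrix genes fell in 11 of 37 cases with 0 higher (25 and 1 adjusted over the list alone), with a median of -2.05 and a camera adjusted p of 1.75e-12 (adjusted p = 0.573 with an estimated correlation). The basement membrane gene FBLN1 fell by 5.22 (adjusted p 0.00992), the proteoglycan gene DCN by 3.27 and LOXL2, a collagen crosslinking enzyme, by 3.22. Without sh-NTC replicate 1, 0 matrix genes passed, and 35 were lower without proliferating replicate 2. Contractile and TGF-beta/YAP-responsive genes moved both ways, with 2 of 21 higher and 6 lower (4 and 8 adjusted over the list alone, median -0.76, camera adjusted p 0.0131; adjusted p = 0.573 with an estimated correlation). CYR61 (-2.69) and LMOD1 (-2.63) fell, and ANKRD1 (3.75) and MYL9, chosen after its values were seen, rose. The contractile call was lost without sh-NTC replicate 1 (0.155), within a range of 1.59e-04 to 0.573.

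The genes furthest apart included IL13RA2, a receptor for interleukin 13 (7.46), and the epithelial transcription factor EHF (7.06) among those that rose. Among those that fell were TMEM176B (-5.41) and FMO2 (-5.50), a flavin monooxygenase. KRT5, a basal epithelial keratin, went from 75 and 184 counts to 0 and 1 (ratio 77.1, interval 13.7 to 3057), and TMSB15A had a ratio of 79.2 (14.1 to 3139). SSTR5-AS1 went from 168 and 511 counts to 2 and 0 (ratio 101, interval 27.9 to 836), but it is antisense to another gene and its level is uncertain.

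Etoposide sh-cGAS and etoposide sh-NTC cells were compared to describe what differed with the hairpin against cGAS in drug-treated cells. The labels name no other hairpin against cGAS, so loss of cGAS cannot be told apart from other effects of this hairpin. The secreted cytokine list was lower in sh-cGAS by camera, with a median log2 fold change of -2.84, and the contractile and matrix lists were higher, with medians of 1.38 and 1.19. These calls were lost with an estimated correlation (adjusted p = 0.452, 0.306 and 0.74), and 0 members of the 3 lists passed over all genes in the 6-library edgeR fit. MMP3 stood at 1677 ± 1343 CPM in sh-NTC and 12.9 ± 2.84 CPM in sh-cGAS (SD, n = 2 each), and MMP1 at 1786 ± 914 and 116 ± 42.7 CPM. The cell cycle lists showed no call, and LMNB1 (8.36 against 8.66 CPM) and CDKN1A (622 against 659 CPM) had close levels.

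In the fit of all 6 libraries edgeR called 0 genes higher and 0 lower between the etoposide groups, with 1371 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.133. Limma-voom and the older edgeR method also called 0, while DESeq2 called 172 higher and 134 lower and library totals without factors gave 59 and 101. Fitted to the 4 etoposide libraries alone, edgeR called 234 higher and 148 lower among 13450 tested, with 3000 at an unadjusted p under 0.05, and 214 of these 382 genes were also called by DESeq2 in 6 libraries in the same direction. In the 6-library fit the counts became 239 and 132 without proliferating replicate 1 and 234 and 134 without its replicate 2. They became 0 and 2 (IL33 and MMP3) without sh-NTC replicate 2, and stayed at 0 without sh-NTC replicate 1 or either sh-cGAS library (542, 780 and 572 genes at an unadjusted p under 0.05). In the 4-library fit they were 315 and 245 without sh-NTC replicate 1, 797 and 722 without its replicate 2, and 0 without sh-cGAS replicate 1 or 2 (2207 and 1967 at an unadjusted p under 0.05).

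Of 32 tested secreted cytokines, chemokines and growth factors, 0 passed over all genes in 6 libraries and 23 were lower with 0 higher adjusted over the list alone (camera adjusted p 3.79e-21; adjusted p = 0.452 with an estimated correlation). In the 4 etoposide libraries 7 fell, among them EREG, an EGF receptor ligand (-4.00, SE 0.22, edgeR adjusted p 0.00687), and IL24 (-4.04, adjusted p 0.0395). IL33 had 0 and 1 counts in sh-cGAS against 197 and 35 in sh-NTC, a ratio of 248 with a counting interval of 44.0 to 9818. The number lower in the 4 libraries became 12 without sh-NTC replicate 1, 26 without its replicate 2 and 0 without either sh-cGAS library, and DESeq2 called 11 in 6 libraries. The log2 fold change was -4.73 for IL1A (SE 1.36), -7.18 for IL1B (SE 1.96), -4.65 for IL6, -5.04 for CXCL8, -4.96 for CXCL1 and -1.27 for CCL2, at edgeR adjusted p-values of 0.328, 0.306, 0.424, 0.43, 0.464 and 0.772. Without sh-NTC replicate 1 these became -1.21, -3.65, -0.41, -1.48 and -0.19 for IL1A, IL1B, IL6, CXCL8 and CXCL1, and CCL2 turned to 1.55. For IL1B, DESeq2 gave 0.0151. Over the alternatives the adjusted p ran from 1.13e-09, 3.01e-10, 1.17e-06, 2.21e-06, 3.08e-06 and 0.00254 to 1 for these 6 genes, each lowest in the 4 libraries without sh-NTC replicate 2. IL1B counts were 38 and 9 in sh-cGAS against 5785 and 351 in sh-NTC, and IL6 counts were 190 and 28 against 4862 and 177. The inflammatory counts of sh-NTC replicate 1 stood far above those of replicate 2, and the list's call kept its side of the threshold without any single library.

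Secreted proteases and their regulators were lower by camera (adjusted p 0.00366; adjusted p = 0.948 with an estimated correlation), with a median of -0.10, a mean of -0.80 and 1 higher and 5 lower adjusted over the list alone. In the 4 etoposide libraries MMP3 fell by 7.03 (edgeR adjusted p 0.0167), MMP1 by 3.95 (0.0195), and MMP10 and SERPINB2 also fell, while IGFBP7 rose by 1.59 (0.0195) with TIMP3. MMP10, SERPINB2 and TIMP3 were chosen here after their values were seen. In 6 libraries MMP3 had an adjusted p of 0.133 and MMP1 of 0.159, with ranges of 6.14e-39 to 0.968 and 4.97e-27 to 0.998 over the alternatives. Other NF-kB target genes were lower as a list (median -0.78, camera adjusted p 3.27e-06; adjusted p = 0.926 with an estimated correlation), with 2 lower adjusted over the list alone. In the 4 etoposide libraries IL1RL1, the receptor of IL33 (-2.34), and the kinase gene RIPK2 (-1.72) fell. The number lower there became 4 without sh-NTC replicate 1, 22 without its replicate 2 and 0 without either sh-cGAS library, and DESeq2 called 8 in 6 libraries. The protease counts of 2 higher and 4 lower became 1 and 6 without sh-NTC replicate 1, 5 and 11 without its replicate 2, and 0 without either sh-cGAS library. The NF-kB call was lost without sh-NTC replicate 1 (0.511) or sh-cGAS replicate 2 (0.0914), within a range of 1.52e-24 to 0.982.

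Contractile and TGF-beta/YAP-responsive genes were higher in sh-cGAS (median 1.38, camera adjusted p 5.57e-21; adjusted p = 0.306 with an estimated correlation), with 14 of 21 higher and 0 lower adjusted over the list alone and 10 higher over all genes in the 4 etoposide libraries. ANKRD1, a YAP-responsive gene, rose by 4.18 there (SE 0.69, edgeR adjusted p 0.0358), the intermediate filament gene DES by 3.70 (0.0329) and CNN1, which encodes calponin, by 2.52 (0.0142). Extracellular matrix genes were higher as well (median 1.19, camera adjusted p 1.26e-17; adjusted p = 0.74 with an estimated correlation), with 10 of 37 higher and 0 lower adjusted over the list alone and 12 higher in the 4 libraries. Among the 12 were THBS2 (2.65, SE 0.28), FBLN2 (2.53) and the proteoglycan gene BGN (2.36, SE 0.21). Without sh-NTC replicate 2 the contractile count became 16 and the matrix count 23, with 1 matrix gene lower, and both became 0 without either sh-cGAS library, as did those of the epithelial and smooth muscle markers. Epithelial markers were higher (median 1.49, camera adjusted p 5.51e-08; adjusted p = 0.323 with an estimated correlation), with 4 of 8 higher adjusted over the list alone; the simple keratin genes KRT8, KRT18 and KRT19 rose by 4.11, 3.66 and 3.53 in the 4 libraries. Smooth muscle and pericyte markers were higher (median 0.61, camera adjusted p 0.00224; adjusted p = 0.577 with an estimated correlation), with 3 of 9 higher and 1 lower adjusted over the list alone. DES and CNN1 are on both the contractile and the smooth muscle lists, and the smooth muscle call was lost without sh-NTC replicate 2 (0.158), within a range of 7.04e-05 to 0.77. In the 4 libraries DES, CNN1, CSPG4 (1.34) and NOTCH3, chosen after its values were seen, were the 4 that rose.

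The widest differences in the 4 libraries among genes taken by the naming rule were, on the higher side, TNNT2, which encodes a troponin, at 4.54 (SE 0.54, edgeR adjusted p 0.0195) and the natriuretic peptide gene NPPB at 4.52 (0.0488), followed by ANKRD1, KRT8 and DES. On the lower side, after IL33 and MMP3, were IL13RA2 (-5.43, adjusted p 0.0393), the kinase gene PDK4 (-5.22, 0.0215) and TFPI2, an inhibitor of serine proteases (-5.12, 0.0347). All calls named from the 4 libraries were lost without either sh-cGAS library, and 22 of 29 were also called by DESeq2 in 6 libraries.

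Cell cycle, p53 and interferon lists gave no call between the etoposide groups, each with 0 members adjusted over the list alone in 6 libraries. Over all genes 0 of 13998 passed in that fit, so 0 members over all genes held for every list and does not set these apart. In the 4 etoposide libraries 1 interferon-stimulated gene was higher and 0 members of the others passed. The 6-library fit recovered 0% of simulated log2 fold changes of 1, so these results do not show a lack of change. The median was 0.10 for G2/M and mitosis (camera adjusted p 0.28), -0.00 for G1/S and DNA replication (0.941), 0.28 for histones (0.0542), -0.23 for homologous recombination genes (0.35), 0.29 for cell cycle inhibitors (0.28) and 0.14 for interferon-stimulated genes (0.28). It was -0.01 for p53 targets (0.748) with a mean of 0.02 and a test direction of higher, and 0.01 for lamina genes (0.856) with a mean of -0.02 and a test direction of lower. The medians of the G2/M and lamina lists changed sign with library totals alone, and those of the p53 and G1/S lists with RLE factors. Several of these lists passed without 1 library: G2/M lower without sh-NTC replicate 1 (0.00251) and higher without its replicate 2 (5.77e-10) or sh-cGAS replicate 1 (2.48e-04), G1/S without sh-NTC replicate 2 (0.0438), homologous recombination genes without sh-NTC replicate 1 (0.00251), and interferon-stimulated genes without sh-NTC replicate 1 (0.0033) or sh-cGAS replicate 2 (4.43e-04). Histones passed without proliferating replicate 1 (0.045) or 2 (0.0433), sh-NTC replicate 2 (1.13e-04), sh-cGAS replicate 1 (8.69e-04) or the low-count filter (2.82e-04). G2/M (0.00646) and cell cycle inhibitors (0.0253) passed without that filter. IFIT1 had a log2 fold change of 0.62 (edgeR adjusted p 0.678), ISG15 of 0.64 (0.708), CXCL10 of -1.76 (0.727; 0.72 without sh-NTC replicate 1), CDKN1A of 0.08 (0.969), LMNB1 of 0.05 (0.974), MKI67 of 0.10 (0.97), HMGB2 of 0.19 (0.927) and CDKN2A of 0.61 (0.552). In the 4 libraries GBP1, an interferon-induced GTPase, rose by 1.62 (adjusted p 0.0399). The cGAS-STING list had a median of -0.07 (camera adjusted p 0.28), and its 1 member lower adjusted over the list alone was cGAS. Antigen presentation genes had a median of 0.31 (0.5), with 0 adjusted over the list alone, and passed without sh-NTC replicate 1 (0.0302) or sh-cGAS replicate 2 (0.00285). For each list that passed in this way the highest adjusted p over the alternatives lay between 0.981 and 0.993.

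**Figure D2:**
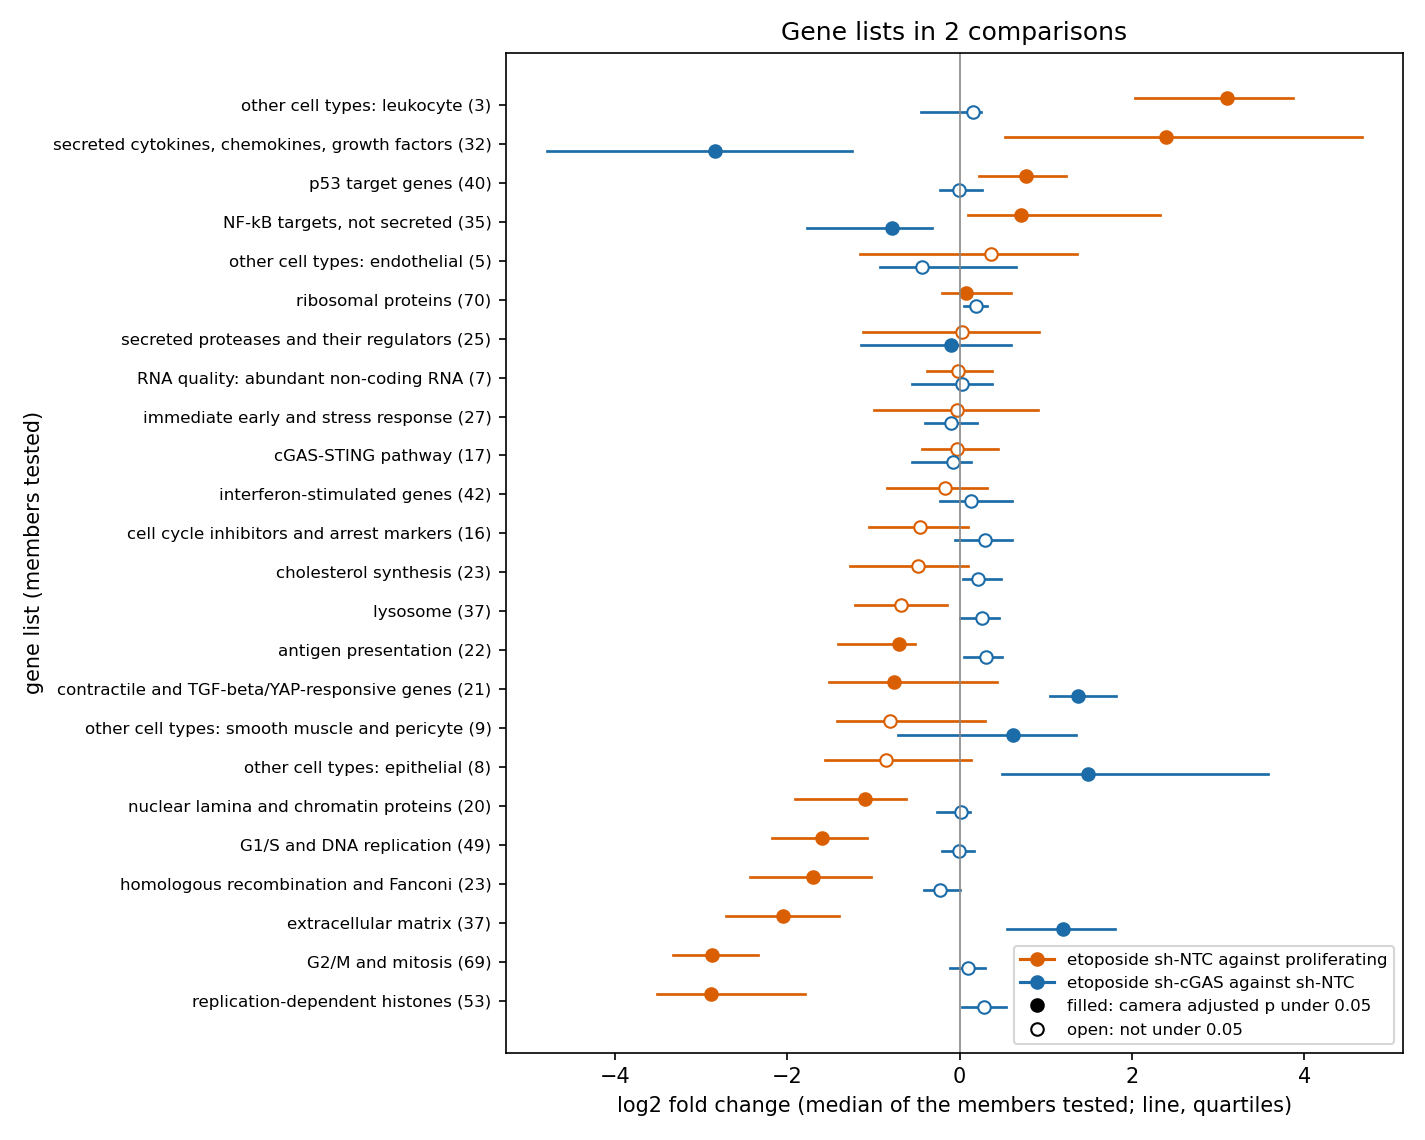
Median log2 fold change of each of 24 gene lists, with a line from the lower to the upper quartile of its members, for sh-NTC against proliferating (orange) and sh-cGAS against sh-NTC (blue); filled points had a camera adjusted p under 0.05. The mitosis and histone lists lie at -2.88 in the first comparison and at 0.10 and 0.28 in the second, and the secreted factors at 2.40 and -2.84.

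Genes that differed between sh-NTC and proliferating cells (the etoposide step) were compared with genes that differed between sh-cGAS and sh-NTC (the second step). Using the calls of the 4 etoposide libraries, 64 genes were higher in sh-NTC than in proliferating cells and lower in sh-cGAS than in sh-NTC, and 95 genes were lower and then higher. Another 9 were higher in both steps and 0 lower in both. Independent lists of these sizes would share 9.32, 15.6, 14.7 and 9.88 genes. Across 20 simulations in which sh-cGAS equalled sh-NTC, the first 2 counts averaged 1.5 (0 to 6) and 0.25 (0 to 2). Those simulations called on average 2.6 genes higher and 2.35 lower in the second step, against 234 and 148 observed, so their overlaps were low for lack of calls and do not show what chance gives at the observed numbers. In the 6-library fit the overlaps were 0 and 0, because edgeR called 0 genes in the second step (1371 at an unadjusted p under 0.05), and with DESeq2 they were 77 and 95. They became 66 and 131 without proliferating replicate 1 and 66 and 148 without its replicate 2. Across genes, which are not independent replicates, the 2 fold changes in 6 libraries had a Pearson correlation of -0.421 against a simulated -0.144 and a covariance of -0.398 against -0.0779, a difference of -0.321. The simulated sh-NTC pairs varied less than the real pair, which on its spread alone would give a covariance of -0.0891 against -0.0779 in the simulations, and the simulations called 1509 and 1827 genes in the etoposide step against 882 and 941. The sh-NTC libraries enter both steps and are too few to split, so part of the excess may come from the shared libraries.

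Etoposide sh-cGAS cells were also compared with proliferating cells. Of the G2/M, G1/S and histone genes 60 of 69, 30 of 49 and 38 of 53 fell, and 13 of 40 p53 targets rose (adjusted p = 0.296, 0.296, 0.345 and 0.149 for these lists with an estimated correlation). CDKN1A rose by 2.16, CDKN2A by 1.72 and MMP3 by 3.71 (SE 0.66). The secreted cytokine list gave no call here (median -0.42). ANKRD1 rose by 7.93 (SE 0.91), MYL9, a myosin light chain gene, by 3.17 and the keratin gene KRT18 by 4.46, whereas the keratin gene KRT5 and the myosin kinase gene MYLK fell. In all, 615 genes were higher and 749 lower (edgeR), DESeq2 called 869 and 1333, and 445 of the higher and 526 of the lower genes were also called in sh-NTC against the same proliferating libraries. The counts became 0 without sh-cGAS replicate 1 or 2 (2596 and 2129 genes at an unadjusted p under 0.05), 1306 and 1367 without proliferating replicate 1, 2393 and 2978 without its replicate 2, 258 and 344 without sh-NTC replicate 1, 232 and 328 without its replicate 2, and 244 and 339 with the sh-NTC group left out. With all 6 libraries, 4129 genes had an unadjusted p under 0.05. The depth and ribosomal RNA share differed between these groups as above.

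In this comparison 60 of 69 G2/M and mitosis genes fell (68 adjusted over the list alone, median -2.80, camera adjusted p 6.76e-58; adjusted p = 0.296 with an estimated correlation), and MKI67 fell by 4.19. Of 49 G1/S genes 30 fell (40 lower and 1 higher adjusted over the list alone, median -1.66, camera adjusted p 6.43e-21; adjusted p = 0.296 with an estimated correlation) and TK1 fell by 3.41. Histones fell in 38 of 53 cases (42 adjusted over the list alone, median -2.63, camera adjusted p 2.32e-31; adjusted p = 0.345 with an estimated correlation). Homologous recombination and Fanconi genes fell in 16 of 23 (21 adjusted over the list alone, median -1.95, camera adjusted p 5.8e-15; adjusted p = 0.296 with an estimated correlation) and FANCA had a log2 fold change of -3.06. Lamina and chromatin genes fell in 8 of 20 (14 adjusted over the list alone, median -1.34, camera adjusted p 7.14e-09; adjusted p = 0.296 with an estimated correlation), LMNB1 by -3.75 and HMGB2 by -2.77. Of 40 p53 targets 13 rose (17 adjusted over the list alone, median 0.88, camera adjusted p 1.9e-08; adjusted p = 0.149 with an estimated correlation), BTG2, an antiproliferative gene, by 2.12. CDKN2B, which encodes the inhibitor p15, rose by 3.18 with CDKN1A and CDKN2A, while CDKN2C (-2.38), RBL1, and RBL2, chosen after its values were seen, fell; the arrest list gave no call (3 higher and 3 lower over all genes and adjusted over the list alone, median -0.32, camera adjusted p 0.693).

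Of the 32 secreted factors, CXCL12, a chemokine of fibroblasts (-4.38), and EREG (-1.55) fell, and 2 were higher and 4 lower adjusted over the list alone (camera adjusted p 0.387). IL1A (-0.38, adjusted p 0.863), IL1B (-2.69, 0.309), IL6 (-1.54, 0.513), CXCL8 (-0.06, 0.983) and CXCL1 (0.57, 0.844) did not pass, nor did MMP1 (0.87, 0.298) or ISG15 (1.28, 0.107). Single libraries set the sign of several of these, with IL1A at 0.54, IL1B at 0.39 and CXCL8 at 2.68 without proliferating replicate 2 and CXCL1 at -2.06 without sh-cGAS replicate 1. Of the proteases, MMP3, SERPINE2 (1.85) and MMP10, chosen after its values were seen, rose (5 and 1 adjusted over the list alone), and the list gave no call (median -0.10, mean 0.13, test direction higher, camera adjusted p 0.678). The protease median turned to 0.03 with library totals alone. Contractile genes were higher (6 up and 3 down of 21, 7 and 3 adjusted over the list alone, median 0.95, camera adjusted p 0.0172; adjusted p = 0.739 with an estimated correlation), a call lost without proliferating replicate 1 (0.0596), its replicate 2 (0.135) or the low-count filter (0.0514), within a range of 3.33e-04 to 0.739. Matrix genes were lower (1 up and 3 down of 37, with the same counts adjusted over the list alone, median -0.96, camera adjusted p 0.0211; adjusted p = 0.976 with an estimated correlation). That call was lost without sh-cGAS replicate 1 (0.0554) and its direction turned without proliferating replicate 1 (0.644), within a range of 5.93e-11 to 0.976. FBLN1 (-3.34), FBLN5 (-2.36) and LOXL1 (-1.76) fell, and MFAP5, chosen after its values were seen, rose. Of the cGAS-STING pathway, cGAS, SAMHD1 (-1.89), RNASEH2A (-1.85) and IFI16, chosen after its values were seen, fell (1 higher and 4 lower adjusted over the list alone, median -0.27, camera adjusted p 0.284). The genes furthest apart included NPPB (7.84), the matrix phosphoprotein gene SPP1 (6.63) and the pigment enzyme gene TYRP1 (6.53) among those that rose, and ADH1B, an alcohol dehydrogenase, which had 161 and 238 counts in proliferating cells against 0 and 1 (ratio 127, interval 22.6 to 5017).

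Epithelial markers moved both ways against proliferating cells, with KRT18 (4.46), KRT8 (4.03), and CDH1 and KRT19, chosen after their values were seen, higher. KRT5 was lower, at a ratio of 41.1 (interval 11.3 to 341) in favour of proliferating cells. Over all genes and adjusted over the list alone 4 of 8 were higher and 1 lower (median 0.83, camera adjusted p 0.145), and the list passed without sh-cGAS replicate 1 (0.0172), within a range of 0.0172 to 0.817. Other NF-kB target genes gave no call (median 0.02, camera adjusted p 0.957), with SAA1, an acute-phase gene chosen after its values were seen (6.84), the 1 member higher, SDC4 (-2.29) the 1 lower, and 0 adjusted over the list alone. Of 42 interferon-stimulated genes UBA7 fell by 2.00 and 0 rose (0 adjusted over the list alone, median -0.09, camera adjusted p 0.471). That list passed without sh-cGAS replicate 1 (0.0109), within a range of 0.0109 to 0.976. Antigen presentation genes had 0 members past the threshold, over all genes and adjusted over the list alone, and a median of -0.61 (camera adjusted p 0.0601). They passed as a list without proliferating replicate 2 (0.00513), sh-NTC replicate 1 (0.0479), sh-cGAS replicate 1 (7.65e-04) or the low-count filter (0.0126), within a range of 7.65e-04 to 0.976.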

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

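The groups, lists and most alternatives were fixed before the data were examined, while the tests in the 4 etoposide libraries other than the 2-group fit and its replicate block, the removal of ribosomal RNA entries, the length correction and the estimated correlation in 4 libraries were chosen only after the result was seen. Where no cause is named, the cause was not tested. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other groups.

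The count of higher or lower genes moved by over 1.5 times in these cases, apart from the length correction in the 4 etoposide libraries. For sh-NTC against proliferating cells (882 higher, 941 lower), the 2 groups alone gave 368 and 356, DESeq2 gave 1603 lower, and leaving out single libraries gave 5 to 2420 higher and 0 to 2910 lower. For sh-cGAS against proliferating cells (615 and 749), the 2 groups alone gave 244 and 339, DESeq2 gave 1333 lower, and leaving out single libraries gave 0 to 2393 and 0 to 2978. For sh-cGAS against sh-NTC (0 and 0 by edgeR, 1371 at an unadjusted p under 0.05), library totals without factors gave 59 and 101, DESeq2 172 and 134, and leaving out single libraries 0 to 239 and 0 to 134. In the 4 etoposide libraries the counts were 234 and 148 with edgeR, 657 and 301 with DESeq2, and 205 and 107 after the length trend was removed. There they were 315 and 245 without sh-NTC replicate 1, 797 and 722 without its replicate 2, and 0 without either sh-cGAS library (2207 and 1967 at an unadjusted p under 0.05). Of the 382 genes called in 4 libraries, 375 were also called by DESeq2 in 4, 300 after the length correction, 341 and 380 without sh-NTC replicate 1 or 2, and 214 by DESeq2 in 6.

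The replicate number was tried as a block because the groups share the numbers 1 and 2. Across genes, which are not independent replicates, the difference between replicates 1 and 2 in sh-NTC correlated with that in sh-cGAS at a Pearson value of 0.32 and a Spearman value of 0.283, but 2 pairs do not show that the numbers pair the cultures. With the block edgeR called 1178 higher and 972 lower in the 4 etoposide libraries, all 382 genes among them, and 0 and 0 in 6 libraries (1110 at an unadjusted p under 0.05), and cGAS stood at -1.67. With the block in 6 libraries the histone list passed between the etoposide groups (camera adjusted p 0.0371, against 0.0542 without it and a range of 1.13e-04 to 0.982 over the alternatives), and no other list call changed.

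The cGAS difference between the etoposide groups passed with the 2 groups alone (-1.67), after the length correction there (-1.67), with DESeq2 there (-1.63), and without sh-NTC replicate 1 (-1.71) or 2 (-1.60) in the 4 libraries, as well as with the block there (adjusted p 0.00507) and without either proliferating library in 6 (0.0407 and 0.0422). It did not pass in the 4 libraries without sh-cGAS replicate 1 (0.211) or 2 (0.226), with DESeq2 in 6 (0.0667), or in the other alternatives. Over all of them the adjusted p ran from 0.00507 to 1, and leaving out single libraries of the 6 gave -1.77 to -1.55.

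Genes higher after etoposide and lower with sh-cGAS numbered 0 in 6 libraries, where edgeR called 0 genes in the second step, 77 with DESeq2, 64 with the calls of the 4 etoposide libraries, and 0 to 66 with single libraries left out. Genes lower and then higher numbered 0, 95, 95 and 0 to 148.

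Of the 24 lists, camera called 13 in sh-NTC against proliferating cells, 7 in sh-cGAS against sh-NTC and 10 in sh-cGAS against proliferating cells. With an estimated correlation it called 0 in each, also in the 4 etoposide libraries, and fry, which asks another question, called 7, 0 and 5. The estimated correlation leaves the test few residual degrees of freedom, so its 0 calls do not show that no list changed. Without the low-count filter 13 were called between the etoposide groups. Leaving out single libraries gave 12 to 15, 9 to 11 and 10 to 12.

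Where the list passed before or after, the direction of 8 list tests turned in 1 setting each, always with a library left out. In sh-NTC against proliferating cells these were cholesterol synthesis (1.42e-05 without proliferating replicate 1) and ribosomal proteins (0.142, the same library). In sh-cGAS against sh-NTC they were G1/S (0.0438 without sh-NTC replicate 2) and G2/M (0.00251 without sh-NTC replicate 1). In sh-cGAS against proliferating cells they were lysosome (0.00636), extracellular matrix (0.644) and ribosomal proteins (0.949) without proliferating replicate 1, and cholesterol synthesis (5.98e-04) without its replicate 2. Over all libraries left out in turn, the adjusted p of these lists ran, in the order given, from 1.15e-05 to 0.741, 3.89e-10 to 0.234, 0.0438 to 0.892, 5.77e-10 to 0.482, 1.73e-05 to 0.908, 5.93e-11 to 0.644, 3.46e-14 to 0.949 and 3.9e-09 to 0.908.

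Of the other list tests, 193, 260 and 207 stayed on the same side of the threshold in the 3 comparisons, in the order above. Turns of direction between tests that did not pass were not counted apart from these. Calls were gained in 17, 26 and 9 tests and lost in 28, 24 and 20, which include those with an estimated correlation. The 68, 59 and 29 called genes that the naming rule took, against proliferating cells in sh-NTC and in sh-cGAS and between the etoposide groups in 4 libraries, kept their sign in the settings that tested them, and genes chosen after their values were seen were not followed through the settings. Of 68 named and called in sh-NTC against proliferating cells, 2 were called without sh-NTC replicate 1 and 32 without its replicate 2, and of 59 in sh-cGAS against proliferating cells, 0 without either sh-cGAS library. Library totals without factors moved the median of all genes by 0.13 in sh-NTC against proliferating cells and the share of higher calls from 48.4% to 54.4%. The 4 etoposide libraries hold fewer counts than the proliferating pair, so a gene at 3 counts there stands at 0.235 to 0.308 CPM.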

Other observations

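The tests of gene length and of leukocytes were set out before their results were seen, and the other tests of explanations here were chosen only after the result was seen. Ribosomal protein genes were higher as a list in sh-NTC than in proliferating cells (8 of 70 higher and 0 lower, over all genes and adjusted over the list alone, median 0.08, mean 0.35, camera adjusted p 0.0158; adjusted p = 0.81 with an estimated correlation), with RPL7 at 5.09 (SE 0.40), RPL24 at 2.83 and RPS3A at 2.23. Without proliferating replicate 1 that direction turned (0.142), and the call was lost without sh-NTC replicate 1 (0.234) or the low-count filter (0.328), within a range of 3.89e-10 to 0.81. In sh-cGAS against proliferating cells 8 rose and 0 fell (9 and 1 adjusted over the list alone, median 0.34, camera adjusted p 2.16e-04; adjusted p = 0.976 with an estimated correlation), with the direction turned without proliferating replicate 1 (0.949), within a range of 3.46e-14 to 0.976. Between the etoposide groups the median was 0.18 with 0 members adjusted over the list alone (camera adjusted p 0.106, range over alternatives 4.33e-04 to 0.982). Of 37 lysosomal genes the protease gene CTSS (4.57) and IDS, chosen after its values were seen, rose in sh-NTC over proliferating cells, and the lysosomal hydrolase genes GUSB (-2.64) and LIPA (-2.54) fell (2 and 2 adjusted over the list alone, median -0.68, camera adjusted p 0.115). That list was lower without proliferating replicate 2 (6.29e-08) and without the low-count filter (9.86e-04), within a range of 6.29e-08 to 0.817. GLB1, which encodes the beta-galactosidase assayed as a senescence marker, was at -1.35 (edgeR adjusted p 0.12), a gene chosen after its values were seen. In the 4 etoposide libraries CTSS was lower in sh-cGAS (edgeR adjusted p 0.0336), and LIPA, FUCA1 and LGMN, the last chosen after its values were seen, were higher (0 and 1 adjusted over the list alone in 6 libraries, median 0.26, camera adjusted p 0.265, range 0.00285 to 0.982). In sh-cGAS against proliferating cells FUCA1 rose by 2.28 and GUSB had a log2 fold change of -2.28 (0 adjusted over the list alone, median -0.32, camera adjusted p 0.511), and the list turned higher without proliferating replicate 1 (0.00636) and was lower without its replicate 2 (1.73e-05), within a range of 1.73e-05 to 0.978.

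Cholesterol synthesis genes gave no call in sh-NTC against proliferating cells (median -0.48, camera adjusted p 0.844), where IDI1 rose by 1.60 and 0 of 23 passed adjusted over the list alone. The list was higher without proliferating replicate 1 (1.42e-05) and lower without its replicate 2 (1.15e-05), within a range of 1.15e-05 to 0.953. Against sh-NTC the sh-cGAS median was 0.22 (0 adjusted over the list alone, camera adjusted p 0.28), and against proliferating cells it was -0.23 with a test direction of higher (camera adjusted p 0.697), positive with library totals alone, and IDI1 rose by 1.82 (0 adjusted over the list alone). Of 27 immediate early and stress genes 5 rose and 3 fell in sh-NTC over proliferating cells (6 and 4 adjusted over the list alone), with FOSL1 at 2.24, the asparagine synthetase gene ASNS at -2.62 and KLF6 at -1.81. The list's median of -0.03, with a test direction of higher, gave no call (camera adjusted p 0.694) and turned positive with library totals alone. In sh-cGAS against sh-NTC the median was -0.10 (2 and 2 adjusted over the list alone, camera adjusted p 0.571), and in the 4 libraries KLF6 was higher and HSPA1B lower, at edgeR adjusted p-values of 0.0358 and 0.0406. HSPA1B has a near-identical copy, so its level is uncertain. Against proliferating cells 5 rose and 2 fell in sh-cGAS (6 and 4 adjusted over the list alone, median -0.08, test direction higher, camera adjusted p 0.957), among them FOSL1 (1.65), ASNS (-1.84) and NR4A1 (-2.77). The abundant non-coding RNA list includes a ribosomal RNA entry, while its shares were set against counts without ribosomal RNA. They came to 2.28% and 0.658% in proliferating cells, 6.37% and 5.75% in sh-NTC and 2.77% and 4.55% in sh-cGAS. That entry alone took 1.35% and 0.0425%, 3.91% and 4.4%, and 1.7% and 3.57% of all counts in the same order. The shares therefore do not show a change of the other members. The list gave no call in any comparison (medians -0.02, 0.03 and -0.10, means 0.06, -0.11 and -0.05, camera adjusted p 0.877, 0.918 and 0.957), with RMRP at -1.78 in sh-NTC over proliferating cells the 1 of 7 that fell, over all genes and adjusted over the list alone. The median between the etoposide groups turned negative with library totals alone.

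The leukocyte genes PTPRC (4.62) and LAPTM5 (3.10), both chosen after their values were seen, were higher in sh-NTC than in proliferating cells, but PTPRC had 6, 1, 18, 43, 26 and 56 counts across the 6 libraries and LAPTM5 4, 5, 7, 18, 16 and 12. That list had 3 of 3 higher adjusted over the list alone (median 3.10, camera adjusted p 0.00415; adjusted p = 0.316 with an estimated correlation). In sh-cGAS against proliferating cells 2 were higher (2 adjusted over the list alone, median 3.26, camera adjusted p 0.0148; adjusted p = 0.345 with an estimated correlation), a call lost without proliferating replicate 2 (0.135), within a range of 7.67e-04 to 0.345. Between the etoposide groups the median was 0.16, with a mean of -0.19, a test direction of lower and 0 adjusted over the list alone (camera adjusted p 0.571). In sh-NTC over proliferating cells, KRT5 and MUC1 (-3.05) fell and 0 of 8 epithelial markers rose (1 higher and 2 lower adjusted over the list alone, median -0.85, camera adjusted p 0.165). The epithelial list passed without sh-NTC replicate 2 (0.016), within a range of 0.016 to 0.695. Of 5 endothelial markers TEK fell by 1.76 and VWF, chosen after its values were seen, rose (1 and 1 adjusted over the list alone, median 0.36, camera adjusted p 0.844). It passed without sh-NTC replicate 1 (0.0221), sh-cGAS replicate 1 (0.0452) or the low-count filter (0.0362), within a range of 0.0221 to 0.953. The other comparisons gave endothelial medians of -0.43 and -0.06 with 0 members past the threshold or adjusted over the list alone (camera adjusted p 0.918 and 0.957), the second with a mean of 0.06, a test direction of higher and a positive median with library totals alone. Smooth muscle and pericyte markers gave RGS5 at 5.12 and CSPG4 (-3.06), NOTCH3 (-1.87) and CNN1, chosen after its values were seen, lower in sh-NTC than in proliferating cells (1 and 3 adjusted over the list alone, median -0.81, camera adjusted p 0.185). The list passed without proliferating replicate 2 (0.0249) or the low-count filter (0.0313), within a range of 0.0249 to 0.671. In sh-cGAS against proliferating cells DES and CNN1 rose (2 and 0 adjusted over the list alone, median -0.20, mean 0.31, test direction higher, camera adjusted p 0.631).

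Among the secreted factors that did not pass the low-count filter, the chemokine gene CCL20, chosen after its values were seen, had 2, 26, 638, 8, 8 and 3 counts across the proliferating, sh-NTC and sh-cGAS libraries.

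Between the etoposide groups edgeR called 0 genes in all 6 libraries and 382 in the 4 etoposide libraries. Removing a smooth trend on transcript length from all 6 libraries left 0 calls (1432 at an unadjusted p under 0.05), which argues against such a trend as the whole cause. With proliferating replicate 1 or 2 left out, so that this group adds nothing to the shared spread, 371 and 368 genes passed, and the common dispersion was 0.0985 in all 6 libraries against 0.0401 in the 4. These values are consistent with the hypothesis that the spread between the proliferating libraries sets the 6-library count. Why that pair lies apart stays open, and neither the difference in culture history that the PD29 and PD34 labels may mark nor a batch of preparation was tested.

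Secreted cytokine genes were higher in sh-NTC replicate 1 than in replicate 2, with 30 of 32 members higher and a median log2 ratio of 1.69, against -0.169 to 0.149 for the central 95% of 10000 random lists matched on expression, which argues against scaling or depth. Leukocytes in the culture are argued against as well, since PTPRC, TYROBP, FCER1G and LAPTM5 together had 0.501% of the IL1B count in that library. In sh-cGAS the same list was higher in replicate 1 by a median of 0.64 (random lists -0.154 to 0.156, 23 of 32 members higher). A factor shared by libraries of the same replicate number could give that value. The proliferating pair went the other way (-0.40, random lists -0.351 to 0.492). The list thus left the random range in every pair. Random genes need not move together as genes of this list may, so these ranges cannot show whether such a factor acted. The labels name no such factor, and a biological difference between the sh-NTC cultures stays open and untested.

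RPL7 had 25 and 75 counts in the proliferating libraries and 466, 478, 483 and 639 in the etoposide libraries, although these held fewer counts in all. The other ribosomal protein genes had a median log2 fold change of 0.0702. As a class these genes took 0.568% and 1.95% of the counts without ribosomal RNA in proliferating replicates 1 and 2. In the etoposide libraries the class took 1.61% to 1.88%. The proliferating pair disagrees, so the median does not decide whether the class changed. The class was no lower in proliferating replicate 2 than in any etoposide library, whereas RPL7 was lower in both proliferating libraries. Across 70 ribosomal protein genes, which are not independent replicates, the number of annotated processed pseudogenes correlated with the log2 fold change of sh-NTC over proliferating cells at a Spearman rho of 0.329 (two-sided permutation p 0.00538, 100000 permutations), and the rho between the etoposide groups was -0.0311 (p 0.797), but outside this class the 168 genes with 5 or more pseudogenes had a median of 0.19 against -0.04 for the 12657 with 0 in the first comparison and 0.17 against -0.02 between the etoposide groups. RPL7 has 61 such pseudogenes and RPS3A 38, but RPS10, at 5.07 from 5 and 1 counts in proliferating cells and 37, 30, 26 and 42 in the others, has 10, RPL24 has 4, and RPL7A, with 37, was at 0.06. Reads shared with pseudogenes and counted differently in the 2 sets of libraries may account for part of the RPL7 difference but leave RPL24 and RPS10 open, and an effect of the drug, the hairpin or the time in culture was not tested apart from it.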
